A study of Nannochloropsis gaditana with 4 samples.

How the data were processed

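Transcript quantities of 44 genes were measured by real-time quantitative PCR with SYBR Green, a dye that fluoresces when bound to double-stranded DNA, in the marine microalga *Nannochloropsis gaditana* strain CCAP 849/5. Per the labels' protocols, cells were grown in batch for 13 days in gas-mixed flasks under continuous light (CL) or under flashing light at 5, 50 or 500 Hz with a duty cycle of 0.05. The time-averaged light was 300 µmol s-1 m-2 in every culture condition and the flash itself reached 6000 µmol s-1 m-2. There was 1 sample per condition, and the series' design text states that RNA was pooled before measurement.

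The authors deposited 3 tables of 132 rows, with 3 numbered repeats for each gene. Whether a repeat was a culture, a reverse transcription or a well is not given in the sources used here. The table described as not normalized held a linear ratio per value, deposited relative to the highest of the 12 values of a gene, so that the highest value was 1 in each of the 44 genes. It held no threshold cycles, so the number of cycles behind a value and the distance to the detection limit are unknown. The normalized table held the same ratio after the authors divided it by the signal of housekeeping genes, per the file headers. Recomputation gave the divisor: 1 factor per sample and repeat, equal to the geometric mean of the CYP (cyclophilin) and PAP1 (phosphatidic acid phosphatase) ratios scaled to a geometric mean of 1, which held for 43 genes within 0.1%. The factor ran from 0.757 to 1.49. The deposited fold table held test over control, per the file headers, and 393 of its 396 values equalled the ratio of normalized values within 0.1%. The instrument, the software and the way amplification efficiencies were found are not given in the sources used here. The logarithms of the deposited ratios were whole multiples of 0.01 cycle at 1 amplification base per gene, between 1.91 and 2.17 per cycle with a median of 2.04, so a gene-specific base was applied upstream. The base was above 2 for 34 genes, at 2 within 0.0005 for 1 gene and below it for 9. A base of 2 is perfect doubling.

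Deposited rows departed from this scheme for 2 genes. The normalized row of MCT (malonyl-CoA:ACP transacylase) equalled the normalization factor itself, with a relative difference of at most 5.04e-06, and so held no measurement of MCT. MCT was therefore taken as its own ratio divided by the factor, a choice made after seeing the data. In the authors' deposited fold table, PAP1 in repeat 1 carried the values of CYP in repeat 1, which were 0.958, 0.986 and 0.975, where the authors' deposited normalized table gives 1.04, 1.01 and 1.03.

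The value columns carried only sample numbers. The control column was recognised from the fold table, whose header names test over control and whose divisor was the same column throughout. CL is the only sample that the labels call control. The other 3 columns are therefore the flashing-light samples, but no header ties a column to a frequency and the order of columns was not used. They are called test samples A, B and C, and no statement on frequency is made from them. A single column stands for each condition, so comparisons are between these samples.

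The design chosen before the data were examined called for threshold cycles and, in their absence, for the normalized table, which was therefore the main source. Values were averaged over the 3 repeats on the log2 scale. The error of a change is the root of the summed squared SDs of the repeats in both samples, called the propagated SD, and covers only the spread of the repeats. With 1 sample per condition no test between conditions was made and no p-value is given. A gene was counted as changed when the change was at least 2-fold and exceeded 2 propagated SDs, a rule of size fixed before the data were examined. Data were simulated for A against CL with errors independent between genes, at each gene's repeat SD pooled over the 4 samples. Over 500 simulations of the 36 targets, the rule passed 48.5% of genes with a true 2-fold change, 98.0% at 3-fold and 99.5% at 4-fold. It passed at most 0.0143% of unchanged genes. Deviations shared over genes, described under other observations, were not simulated, so these rates may not hold for the data.

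Of the 44 genes, 7 carried an r before their identifier and usual reference names, and with PAP1, used by the authors in the factor, 8 were treated as reference genes. The remaining 36 were targets, assigned by name to functional lists fixed before the data were examined. KAS, given in the tables as a ketoacyl-CoA synthase, entered the fatty acid synthesis list by its symbol. Lists for carbon fixation, oxidative stress, and light receptors with the cell cycle had no member. By the rule for named genes, with 40 or fewer targets each could be named, in full where it passed the rule of size against CL and otherwise within its list. Gene symbols are those of the tables, and the locus identifiers are not reported here. 4 row identifiers differed between tables and had no effect on the values. A reference genome was not used here, and gene positions are not given.

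Alternatives comprised each reference gene alone, centring on the median target, no reference, the median of the repeats, omission of each repeat, amplification bases of 2 and 1.9, the deposited fold table, and size thresholds of 1.5-fold, 3-fold or 2-fold without the error rule. The alternatives of the 7 genes with the r prefix as reference, MCT as deposited, and the SD of differences within a repeat number were chosen after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.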

Results

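Relative transcript quantities of 36 target genes and 8 reference genes were obtained from *Nannochloropsis gaditana*, a single-celled alga grown for its oils and pigments, under continuous light (CL) and under flashing light at 5, 50 and 500 Hz. Each of the 4 conditions was represented by 1 sample with 3 repeats, and RNA was pooled before measurement, per the series' design text. The mean light was 300 µmol s-1 m-2 throughout. The comparisons therefore address how delivery of the light in flashes relates to transcripts of pigment, lipid, ADP-glucose and nitrogen metabolism. The 3 flashing-light samples are called test samples A, B and C because their columns are not tied to a frequency. Errors are SDs over the 3 repeats or, for a change, the propagated SD. Whether they hold any spread between cultures is not given in the sources used here, and the number of cycles behind each value is unknown.

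The reference genes used for normalization, CYP and PAP1, moved together. The mean log2 difference between them varied by 0.04 over the 4 samples. Its SD over the repeats was 0.14 in CL, 0.12 in A, 0.08 in B and 0.04 in C. After normalization, the range of the sample means was 0.10 log2 for actin (ACT), 0.31 for elongation factor TEF1, and 0.45 for both alpha tubulin AT1 and GAPDH. It was 0.81 for the ubiquitin family gene UFP and 1.88 for beta tubulin BT. BT stood at a log2 change of −1.61 ± 0.81 in test sample A against CL, −1.31 ± 1.34 in B and 0.28 ± 0.87 in C. None of the 8 reference genes passed the rule of size against CL, although BT did in C against A, at 1.88 ± 0.74.

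In test sample A, 5 of the 36 targets changed against CL, 4 of them upward. VCP1, a violaxanthin-chlorophyll protein of the light-harvesting antenna, rose 3.05-fold, from a normalized quantity of 0.371 ± 0.0959 (SD, n = 3) to 1.11 ± 0.0970 (SD, n = 3), a log2 change of 1.61 ± 0.38. VDE2, a violaxanthin de-epoxidase of the xanthophyll cycle, rose 2.39-fold, a log2 change of 1.26 ± 0.11. HAD, the 3-hydroxyacyl-ACP dehydratase of the fatty acid elongation cycle, and POR1, the light-dependent protochlorophyllide oxidoreductase of chlorophyll synthesis, stood at 2.03-fold and 2.00-fold, log2 changes of 1.02 ± 0.17 and 1.00 ± 0.19. Nitrate reductase NR, which reduces nitrate to nitrite, went from 0.666 ± 0.266 (SD, n = 3) to 0.156 ± 0.0227 (SD, n = 3), a log2 change of −2.03 ± 0.58. Each of these 5 moved the same way in 3 of 3 repeats, which their selection on the same repeats favours. Over all 36 targets, 18 were higher and 8 lower in 3 of 3 repeats.

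**Figure D1:**
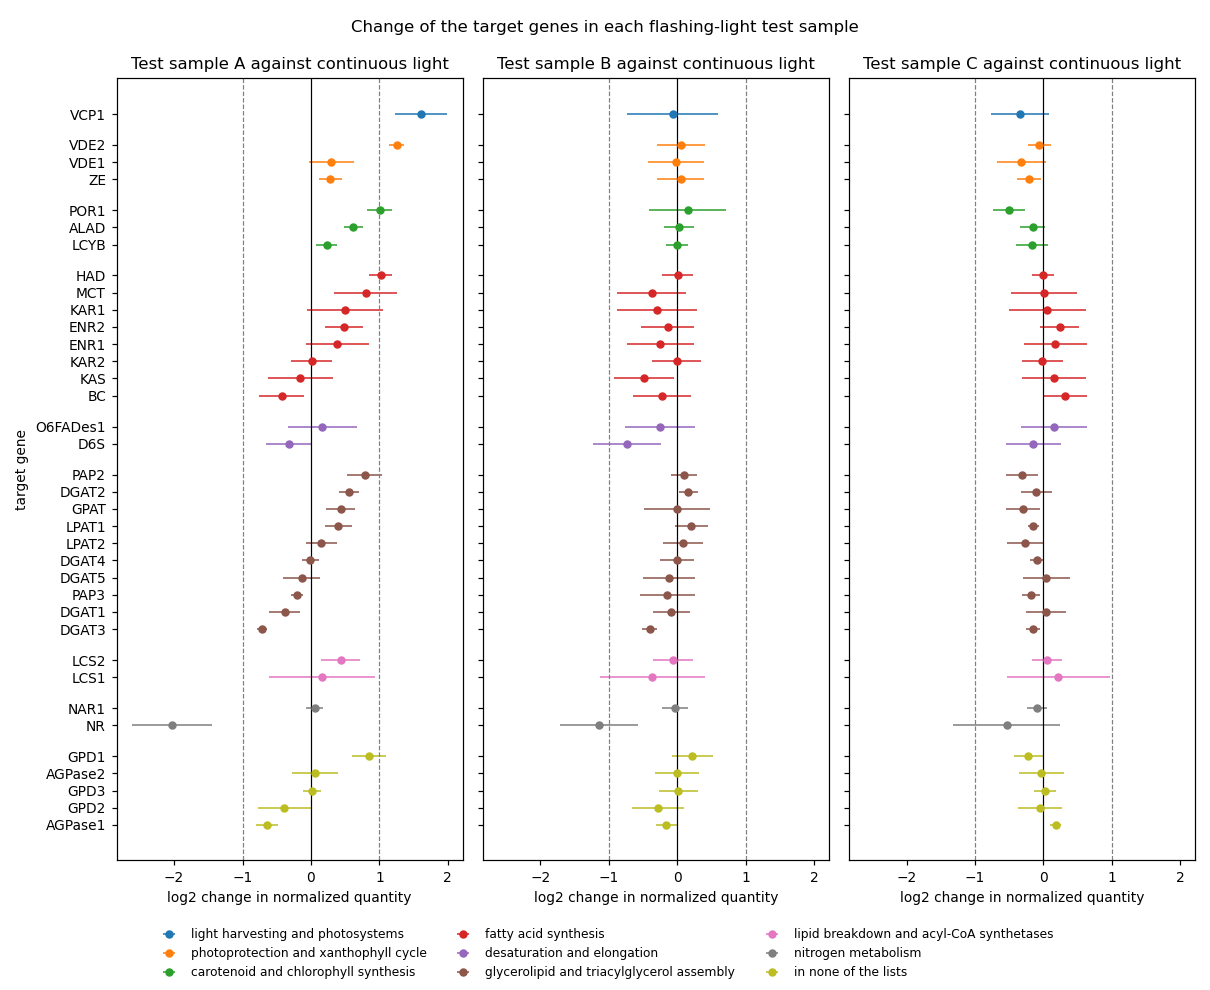
Log2 change in normalized quantity (x axis) of the 36 target genes (y axis, coloured by functional list) in each test sample against continuous light, with bars of 1 propagated SD over the 3 repeats and dashed lines at a 2-fold change. VCP1 at 1.61 and NR at −2.03 lie farthest out in test sample A, whereas in test sample C no point lies beyond a dashed line.

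By functional list, no list had more than 1 member that passed in test sample A. VCP1 was the only member measured for light harvesting. Of the 3 photoprotection genes, VDE2 rose and the other two did not pass, with VDE1 at 0.30 ± 0.33 and ZE, given in the tables as zeaxanthin de-epoxidase, at 0.28 ± 0.17. The carotenoid and chlorophyll list of 3 had a median of 0.62. POR1 rose, ALAD of tetrapyrrole synthesis was at 0.62 ± 0.13 and lycopene beta cyclase LCYB at 0.23 ± 0.15. In fatty acid synthesis 1 of 8 genes rose, HAD, and the median was 0.44. Malonyl-CoA:ACP transacylase MCT was at 0.80 ± 0.46 and the biotin ligase BC at −0.43 ± 0.33. None of the 10 genes of glycerolipid and triacylglycerol assembly passed, and their median was 0.07. The extremes of that list were phosphatidic acid phosphatase PAP2 at 0.78 ± 0.25 and diacylglycerol acyltransferase DGAT3 at −0.72 ± 0.08. Neither desaturase (O6FADes1 at 0.17 ± 0.50, D6S at −0.32 ± 0.33) nor acyl-CoA synthetase (LCS1 at 0.16 ± 0.77, LCS2 at 0.43 ± 0.29) passed. The nitrite transporter NAR1 stood at 0.05 ± 0.12 beside the lower NR. Among genes in none of the lists, glycerol-3-phosphate dehydrogenase GPD1 was at 0.85 ± 0.25 and AGPase1, of the enzyme that makes ADP-glucose, at −0.64 ± 0.16. Both were beyond 2 propagated SDs but under 2-fold, as were 7 other targets.

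VCP1 and NR had the largest fold changes and passed most often. VCP1 passed in each of 19 alternative calculations and NR in 18, the exception being BT as reference with −0.42. Among the 19, the deposited fold table and MCT as deposited leave the log2 changes of the called genes as they are. CYP alone and PAP1 alone are parts of the main factor. VDE2 passed in 17, HAD in 13 and POR1 in 11, and POR1 was at 0.89 without repeat 1. With an amplification base of 2 for every gene, HAD at 0.992 and POR1 at 0.985 fell just under 2-fold. The count of 4 higher and 1 lower became 2 and 1 with ACT alone or with no reference and no centring, 1 and 3 with UFP alone, 1 and 2 after centring on the median target, and 27 and 0 with BT alone.

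**Figure D2:**
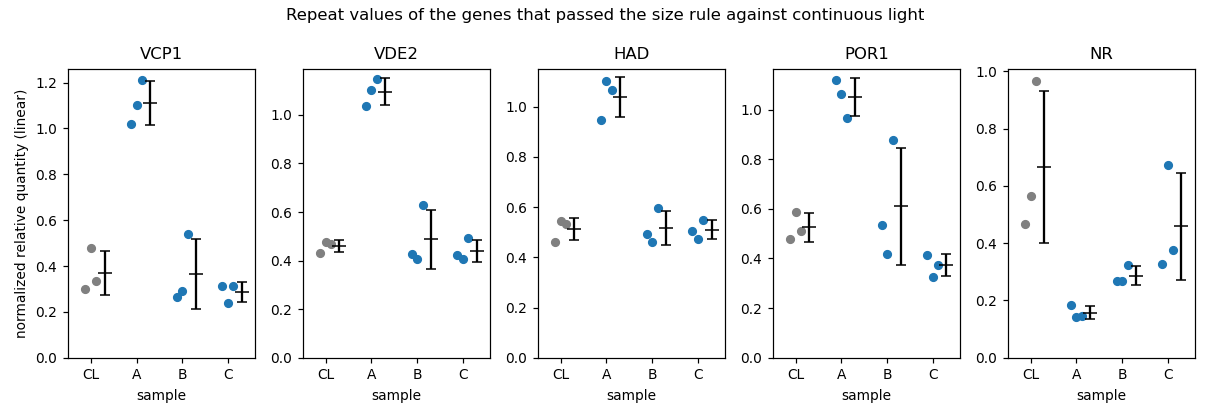
Normalized relative quantity (y axis, linear, from 0) of the 5 genes that passed the rule of size against continuous light, by sample (x axis), with a point per repeat and, beside the points, the mean and a bar of 1 SD (n = 3). The 3 repeats of VCP1 in test sample A lie between 1.02 and 1.21 and those of continuous light between 0.298 and 0.480, and 1 repeat of NR in continuous light lies at 0.968.

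In test sample B, NR alone changed against CL, and only just. NR stood at 0.451-fold, a log2 change of −1.15 ± 0.57, with a normalized quantity of 0.287 ± 0.0325 (SD, n = 3). It was lower in 3 of 3 repeats, as were 10 of the 36 targets with NR counted. The antenna and pigment genes that were higher in A were near the control here, with VCP1 at −0.07 ± 0.66, VDE2 at 0.06 ± 0.35 and POR1 at 0.15 ± 0.56. The 8 fatty acid synthesis genes had a median of −0.23, with HAD at 0.01 ± 0.23 and the ketoacyl-CoA synthase KAS at −0.49 ± 0.44, and none passed. The medians were 0.05 for photoprotection, 0.02 for carotenoid and chlorophyll synthesis and 0.00 for glycerolipid assembly, with no member passing. In the last list DGAT3, at −0.40 ± 0.11, was the only target besides NR beyond 2 propagated SDs. The desaturases were at −0.73 ± 0.50 (D6S) and −0.25 ± 0.51 (O6FADes1), the acyl-CoA synthetases at −0.36 ± 0.76 (LCS1) and −0.06 ± 0.29 (LCS2). NR did not pass without repeat 2, at −1.19 ± 0.77, or without repeat 3, at −0.94 ± 0.19. It passed in 8 of 19 alternative calculations and stood at 0.16 with BT as reference.

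In test sample C, none of the 36 targets changed against CL by the rule of size, and the median target was at −0.08. POR1 at −0.50 ± 0.23 and AGPase1 at 0.18 ± 0.09 were beyond 2 propagated SDs and under 2-fold. VCP1 stood at −0.35 ± 0.42, VDE2 at −0.06 ± 0.17, HAD at 0.00 ± 0.17 and NR at −0.54 ± 0.78. List medians were −0.21 for photoprotection, −0.17 for carotenoid and chlorophyll synthesis, 0.11 for fatty acid synthesis and −0.15 for glycerolipid assembly. The members of these lists ran from −0.50 for POR1 to 0.32 for BC. The desaturases were at 0.15 ± 0.49 (O6FADes1) and −0.15 ± 0.41 (D6S), the acyl-CoA synthetases at 0.22 ± 0.75 (LCS1) and 0.05 ± 0.22 (LCS2).

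The test samples were also set against each other. Against A, test sample B was lower in 4 targets, VCP1 at −1.68 ± 0.57, VDE2 at −1.19 ± 0.35, MCT at −1.17 ± 0.22 and HAD at −1.01 ± 0.22. MCT did not pass against CL in either sample. Test sample C was lower than A in 6 targets, with VCP1 at −1.95 ± 0.26, POR1 at −1.50 ± 0.20, VDE2 at −1.32 ± 0.17, PAP2 at −1.10 ± 0.21, GPD1 at −1.07 ± 0.17 and HAD at −1.02 ± 0.15, and higher in NR at 1.49 ± 0.59. Between C and B no target passed, and the members beyond 2 propagated SDs included KAS at 0.64 ± 0.30 and ENR1 at 0.42 ± 0.20. Direction depended on the reference for these counts. For B against A, 1 target was higher and 1 lower with UFP alone, after centring on the median target, or with no reference, and 1 higher and 3 lower with AT1. For C against A, 7 were higher and 1 lower with UFP alone, 3 and 3 after centring, 1 and 2 with no reference, 0 and 31 with BT, 0 and 11 with GAPDH, and 0 and 9 with the 7 genes with the r prefix.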

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

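Leaving out each repeat was planned before the data were examined. The tests on values centred on the median target, the bounds applied to the left-out repeats, and the count over references given for the picked-out genes were chosen after the results were seen. A gene was picked out here when its change against continuous light, taken within each repeat number, went one way in the 3 repeats of 1 test sample and the other way in the 3 of another. None of these differences was tested, since each condition had 1 sample. Of 108 checks, 11 met this condition. The repeat numbers did not meet the condition set for pairing the samples and the control repeats are shared, so no count for chance is given. In 5 of the 11, AGPase1, LPAT1, POR1, PAP2 and ZE in A against C, both test samples lay apart from every control repeat whatever the matching. Both directions stayed as stated under all 11 alternatives of the reference for POR1 and PAP2, under 10 for AGPase1 and GPAT in A against C, 9 for ZE, BC, DGAT1 and MCT, 8 for LPAT1, and 6 for AGPase1 in B against C. Each value is the log2 change of the first sample minus that of the second.

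Most cases set test sample A against C. In chlorophyll synthesis POR1 was higher in A and lower in C, with a difference of 1.4995. Among glycerolipid genes the same direction held for PAP2 with 1.10, GPAT with 0.73 and LPAT1 with 0.54, and DGAT1 was at −0.38 in A and level with the control in C at 0.04 ± 0.29, a difference of −0.42. ZE of the xanthophyll list was higher in A, with 0.49, but lay below the control in A with UFP as reference, at −0.32, and after centring on the median target. With UFP, LPAT1 and GPAT in A were also below the control, at −0.20 and −0.17. AGPase1 of ADP-glucose synthesis and the biotin ligase BC were lower in A and higher in C, with −0.81 and −0.75. Between B and C the differences were 0.35 for LPAT1 and −0.34 for AGPase1. MCT was higher in A and lower in B when matched by repeat number, with 1.17, from MCT values recomputed as a choice made after seeing the data.

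VCP1, VDE2, HAD and POR1 were higher in test sample A. An error in the reference level would move all targets alike. When the 4 highest targets were chosen in 1 repeat, the choice held 3 of these 4 genes each time. Their median in the other repeats, centred on the median target, was 0.74 or more. That was beyond 2 of their median propagated SDs whichever repeat was used, but narrowly with repeat 1, at 0.75 with an SD of 0.36. That SD is of single genes, not of the median of 4. The median of the 4 named genes stayed at 1.13 or more whichever repeat was left out. Those genes were called from the same 3 repeats, so that value says little on whether 1 repeat deviated. Centring shifted each target down in A and left VCP1 as the only one of the 4 that passed, at 1.28 ± 0.43, with VDE2 at 0.93 ± 0.13, HAD at 0.69 ± 0.16 and POR1 at 0.68 ± 0.24 under 2-fold, so the size of their change depends on the reference. A response of these 4 transcripts to 1 of the flash regimes may be behind the pattern, but remains an untested hypothesis, and differences between cultures stay open.

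NR was lower than continuous light in test samples A and B. In A, NR centred on the median target was at −2.35 ± 0.51, which argues against a reference error as the whole cause. Its change was −1.67 or lower whichever repeat was left out, although NR was called from these same repeats. In B the centred value was −1.06 ± 0.45, beyond 2 propagated SDs by a small margin, so the argument against a reference error is weak there. With BT alone as reference NR in B stood at 0.16. Its change was within 2 propagated SDs without repeat 2, at −1.19 ± 0.77, and under 2-fold without repeat 3, at −0.94 ± 0.19. A single repeat behind the call in B therefore stays open. In C the lower mean rested on repeat 3, without which NR stood at −0.13, and the centred value of −0.58 was within its error, so a reference error cannot be told apart there. Nitrogen supply and the time of harvest were not tested, so a light response in A or B remains a hypothesis.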

How the results depend on the processing

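Alternatives chosen after seeing the data were the 7 genes with the r prefix as reference, MCT as deposited and the SD within repeat numbers. Over 23 alternatives, 421 of 536 values moved by less than their spread or, for counts, by less than 1.5 times, 114 moved further and 1 called gene value reversed: NR in B against CL, 0.16 with BT alone. Apart from called genes, 32 of 228 list medians changed sign. Some of the 421 were fixed in advance, since MCT as deposited and the deposited fold table leave the log2 changes of the called genes as they are. C against CL gave 0 genes in each of the 23. The reference moved the median target in A by −0.60 (UFP) to 1.61 (BT), and such a shift is the same for each gene. No late-cycle filter was run, as no threshold cycles were used here, and depth limits are unknown. Causes of the changes below were not tested beyond what each setting fixes. Counts are of genes passing, and medians are log2 in the order photoprotection, carotenoid and chlorophyll, fatty acid, glycerolipid. Taking differences within a repeat number, as a replicate block would, left each count as it was. Repeat numbers did not meet the pairing condition: correlations ran from −0.38 to 0.55, 10 of 18 above 0.1.

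A against CL gave 3 genes (main 5) with ACT alone, base 2, base 1.9, centring on the median target and no reference, 27 with BT, 9 with GAPDH, 8 with the 7 genes, 10 at 1.5-fold and 2 at 3-fold. B against CL gave 0 (main 1) with PAP1, TEF1, UFP, AT1, BT, GAPDH, the 7 genes, no reference, the median of repeats and 3-fold, and 0 to 1 with 1 repeat left out (0 without repeat 2 or 3). B against A (main 4) gave 1 with BT, 2 with UFP, centring or no reference, 11 at 1.5-fold and 1 at 3-fold. C against A (main 7) gave 31 with BT, 11 with GAPDH, 4 with base 1.9, 3 with no reference, 14 at 1.5-fold and 1 at 3-fold. C against B (main 0) gave 2 with BT and 1 at 1.5-fold.

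List medians that moved, in A: TEF1 0.60, 0.92 and glycerolipid 0.37. AT1 0.62, 0.94 and glycerolipid 0.39. GAPDH 0.74, 1.06, 0.87, 0.51. The 7 genes 0.59, 0.91 and glycerolipid 0.36. BT 1.91, 2.23, 2.04, 1.68. UFP −0.30, 0.022, −0.16, −0.53. Centring −0.026, 0.30 and glycerolipid −0.25. No reference 0.12, 0.44. In B: TEF1 carotenoid 0.26. GAPDH carotenoid 0.27. The 7 genes carotenoid 0.35 and glycerolipid 0.32. AT1 0.50, 0.48, 0.22, 0.45. BT 1.36, 1.34, 1.08, 1.31. In C: AT1 −0.015 and UFP −0.0021 for photoprotection, and BT −0.49, −0.45 and glycerolipid −0.42.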

Other observations

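The tests in this part were chosen after the data were seen. Several enzymes were measured as 2 or more genes. The ratio of such a pair does not depend on the reference genes, except in pairs that hold the reference gene PAP1. In test sample A, 13 of the 22 pairs that can be formed within the 9 such families, with the reference gene PAP1 counted in its family, shifted against continuous light by more than 2 propagated SDs, each with its 3 repeats outside the range of the control repeats. These were 7 of 10 DGAT pairs, 2 of 3 GPD pairs, 2 of 3 PAP pairs and the 1 pair each of VDE and AGPase, and pairs within a family share genes. The PAP pairs among them include PAP1 to PAP2, at −0.77 ± 0.16, which sets PAP2 against a reference gene. In A, 14 of the 36 single targets were also beyond 2 propagated SDs. Pairs of unrelated genes were not counted, so the 13 is not shown to be particular to these families. The 2-fold part of the rule of size was not applied to ratios, and of the 13 only DGAT2 to DGAT3 and GPD1 to GPD2 reached 2-fold. The pairs named below were picked from the 13 after their values were seen. The ratio of diacylglycerol acyltransferases DGAT2 to DGAT3, of the last step of triacylglycerol synthesis, was 2.42-fold that of the control, a log2 change of 1.28 ± 0.17. The ratio of glycerol-3-phosphate dehydrogenases GPD1 to GPD2 was 2.37-fold, at 1.25 ± 0.51, and that of phosphatidic acid phosphatases PAP2 to PAP3 was 1.98-fold, at 0.98 ± 0.23. For the violaxanthin de-epoxidases, VDE1 to VDE2 was 0.516-fold, at −0.96 ± 0.34. The ratio of AGPase1 to AGPase2 was 0.616-fold, at −0.70 ± 0.32. Which gene stands first in a pair is arbitrary, so directions are not compared between pairs. The KAR, ENR, LPAT and LCS pairs stayed within 2 propagated SDs.

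In test sample B, 2 of these 22 pairs were beyond 2 propagated SDs, DGAT2 to DGAT3 at 1.48-fold and 0.57 ± 0.17, and DGAT3 to DGAT4 at −0.40 ± 0.15. In C there were 0, with DGAT2 to DGAT3 at 0.04 ± 0.20. The difference between samples was not tested. The members of a pair share no control for primer quality, so a shift in a ratio says that 2 amplicons changed unequally, not which of them changed.

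The repeats of a sample deviated together over genes. The first principal component of the deviations of the 36 targets from their sample means held 43.2% of the variance, above the highest of 10000 shuffles of the repeats within gene and sample, 42.3%, with a median of 29.8%. Errors that are independent between reactions are therefore not enough. Subtracting the median target of each sample and repeat, which takes out an error of the 2 reference genes, removed 20.8% of the variance, and the first component then held 48.4% of the rest, against at most 41.9% in 10000 shuffles centred the same way. Such an error is therefore not the whole of the pattern. LCS1, D6S and KAS had the highest loadings. Repeat 3 scored highest in each of the 4 samples, at 0.53, 0.14, 0.52 and 0.21 for CL, A, B and C, and repeat 1 scored below 0 in each, at −0.31, −0.17, −0.11 and −0.20, so an effect shared by repeat number stays open. A difference between RNA or cDNA preparations may be shared by genes in this way, but was not tested, and no biological explanation was tested.

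The changes of test samples A and C against continuous light correlated across genes at −0.07 (Pearson) and −0.22 (Spearman), where genes are not independent replicates. Without NR, left out after its value was seen, the correlation was −0.40, so the value rests largely on that gene, and B with C gave −0.07. A with B gave 0.67, and 0.46 without NR, which was lower in both. The shared control alone was simulated with no effect, 10000 times. Mean correlations were then 0.77 for A with C, 0.66 for A with B and 0.62 for B with C. The 0.67 of A with B is thus near what a shared control gives without any effect. Changes in 1 of the samples would alter that value, so the simulation cannot decide whether A and B share a response. The −0.07 of A with C was below the lowest simulated value, 0.09. Changes in A unrelated to those in C would also lower the correlation, so opposed responses do not follow from it. The simulated covariance for A with C had a mean of 0.03 and ran from 0.0026 to 0.121. The covariance of A with C was −0.01, below that range, and −0.04 without NR. That of A with B was 0.117, and 0.05 without NR, both within the range for A with C. The simulated range leaves out the spread that real changes would add, so it decides neither a shared nor an opposed response. None of these differences was tested.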
